A study of Mus musculus with 21 samples.

How the data were processed

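RNA from cells sorted by green fluorescent protein (GFP) was measured on 21 Affymetrix mouse arrays, short-oligonucleotide arrays on which a probe set stands for a transcript. Per the labels, each array holds cells sorted from 3 pooled dissections of mouse telencephalon at E14.5 (embryonic day). The labels give 3 groups: GFP-positive cells of the cortex (10 arrays), GFP-negative cells of the cortex (5 arrays) and GFP-positive cells of the ganglionic eminences (6 arrays). The descriptions were followed where another label names the cortex for every array. The title of 1 array names a labelling kit. The labels do not say which gene drives GFP, which arrays share a litter, a sort or a labelling day, or whether replicates are separate litters. The p-values therefore measure the spread between these arrays, which may be partly technical. Cortex GFP-positive replicates 6, 9 and 10, and replicates 7 and 8, were near-identical and may be repeats of the same RNA. If so, n = 10 in that group stands for 7, n = 8 without replicates 7 and 8 for 6, and the SDs and SEs are too small. Replicates 7 and 8 were also close to ganglionic eminence replicate 5. If they repeat the RNA of that array, n = 10 stands for 6 cortex RNAs, and the same RNA enters both GFP-positive groups. Replicate numbers were given here in accession order and name an array only.

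The authors deposited a table of linear intensity values for 45101 probe sets, with no missing value. The software and its scaling are not given in the sources used here. The mean of each array without its highest and lowest 2% was 2499 on every array, so the values had been scaled to a common level, and no further step between arrays was added. Deposited intensity values ran from 0.300 to 341634. No value per array of background or detection was used here, and the number of arrays limits the precision.

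Intensities were put on the log2 scale as log2(intensity + 16), so that a fold difference is on that scale and understates the change of dim genes. A probe set was kept if it lay above the 40th percentile of its own array on at least 5 of the 21 arrays, whatever the group, which left 31056. The 64 control probe sets were left out. In the platform annotation used here 34958 probe sets carried 1 gene symbol, 932 several and 9211 none. Symbols were compared with a current gene table through the Entrez number, and 0 changed. A gene named by exactly 1 symbol was represented by its kept probe set with the highest mean over all 21 arrays, which gave 13668 genes. Among the named genes, no other kept probe set passed the threshold in the opposite direction.

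Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 21 arrays, then eBayes with an intensity trend), two-sided. P-values were adjusted by Benjamini-Hochberg over the 13668 genes, with a threshold of 0.05. Where the mean of the dimmer group lay under the mean 40th percentile of its arrays for a gene, or at least as many of its arrays lay under their own as above it, the fold was given as "at least", with that percentile in place of the dimmer signal on each array where it was the higher. This rule first covered groups with every array under it and was widened after seeing the data, and list medians were also computed with both groups floored in that way. The comparisons were cortex GFP-positive against cortex GFP-negative, cortex GFP-positive against ganglionic eminence GFP-positive, and ganglionic eminence GFP-positive against cortex GFP-negative. In the last, region and reporter differ together.

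There were 18 gene lists, fixed from textbook knowledge before the data were examined: GABAergic lineage, interneurons derived from the medial ganglionic eminence (MGE), interneurons derived from the caudal ganglionic eminence (CGE), striatal projection neuron, cortical projection neuron, pallial progenitor, radial glia, cell cycle, Cajal-Retzius, axon guidance and migration, GABA and glutamate receptors, endothelial, mural and meningeal, microglia, erythroid, oligodendrocyte lineage, immediate early and stress, and apoptosis. Of their 416 genes 357 were measured, and some stand in more than 1 list. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over 54 tests (18 lists in 3 comparisons). Camera with an estimated correlation and fry were run beside it. Camera asks whether a list differs from the other genes, while fry asks whether its genes differ from no change. A result with fry is therefore not the same call. The named genes followed a rule fixed before the data were examined. It takes, per comparison, the 8 highest and 8 lowest log2 differences among genes past the threshold with a mean at or above the median gene, 20 fixed marker genes whatever their result, and up to 4 members of each list with the smallest adjusted p. The text names a part of these. These were chosen after the values were seen, for the groups they belong to. Of the 20 marker genes, 2 were not analysed here, since no probe set carried their symbol in the annotation used.

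RNA quality was measured on each array as the mean log2 ratio of the 3' to the 5' control probe set of Gapdh and Actb, and compared by two-sided exact permutation tests. The signal of the 5' control probe set of 18S ribosomal RNA fell into 2 classes with a gap from 12.00 to 14.63 on the log2 scale. The high class held 8 arrays (3 cortex GFP-positive, 3 cortex GFP-negative and 2 ganglionic eminence) and the low class 13 (7, 2 and 4). Since the classes crossed the groups, comparisons were repeated with the class as a term and within each class. The alternatives planned before the data were examined were quantile normalization, median centring, other pseudocounts and filters, other eBayes settings, array weights, fits of the compared groups only, the mean of a gene's probe sets, counting probe sets, an RNA quality covariate, stricter thresholds, and each array left out in turn. Alternatives added after seeing the data left out cortex GFP-positive replicates 7 and 8, averaged near-identical arrays, used the 18S class or the Xist signal class (a mark of the sex of the pooled embryos), or used a larger pseudocount.

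The scripts were tested on simulated arrays with the real means and spreads, 13668 genes and 50 changed genes per size of change. For cortex GFP-positive against cortex GFP-negative, 22 of 50 genes changed by 1 on the log2 scale were called, 49 of 50 changed by 2 and 50 of 50 changed by 4, with 3 unchanged genes called. For cortex against ganglionic eminence GFP-positive arrays, the calls were 33, 42 and 50 of 50, with 12 unchanged genes called. For ganglionic eminence GFP-positive against cortex GFP-negative arrays they were 18, 41 and 50 of 50, with 5 unchanged genes called. The simulated noise was independent between genes and held no 18S classes and no near-identical arrays. Far fewer genes were changed than the real comparisons called. The rates therefore check the scripts and are not error rates of these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.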

Results

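Gene expression was measured on 21 arrays of cells sorted from the mouse telencephalon at E14.5 (embryonic day). At this stage GABAergic interneurons born in the ganglionic eminences, the ventral germinal zones, are migrating into the cortex, where glutamatergic neurons are made locally. GFP-positive cells were sorted from the cortex (10 arrays) and from the ganglionic eminences (6 arrays), and GFP-negative cells from the cortex (5 arrays). GFP-positive cells of the cortex were compared with their GFP-negative neighbours and with GFP-positive cells of the ganglionic eminences. Levels are mean log2(intensity + 16) ± SD over arrays, and n counts arrays. Cortex GFP-positive replicates 6, 9 and 10, and 7 and 8, were near-identical and may be repeats of the same RNA. In that case n = 10 stands for 7 and n = 8 for 6, with SDs that are too small. Replicates 7 and 8 were also close to ganglionic eminence replicate 5. If they repeat the RNA of that array, n = 10 stands for 6 cortex RNAs, and the same RNA enters both GFP-positive groups.

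In the cortex, GFP-positive cells carried the transcripts of GABAergic neurons, and GFP-negative cells those of glutamatergic neurons and their progenitors. Gad1, an enzyme that makes GABA, read 15.57 ± 0.22 (n = 10) in GFP-positive and 6.77 ± 1.02 (n = 5) in GFP-negative arrays, at least 241-fold higher (log2 difference 8.80, SE 0.26, adjusted p = 3.03e-18). Slc32a1, the vesicular GABA transporter, was at least 157-fold higher (adjusted p = 3.75e-20). Neurod6, a transcription factor of glutamatergic cortical neurons, was 16.4-fold lower (11.28 ± 1.49, n = 10, against 15.31 ± 0.35, n = 5; adjusted p = 2.74e-06). Of 13668 genes, 4292 passed the threshold, 1938 higher and 2354 lower in GFP-positive arrays, of which 928 and 1370 differed at least 2-fold.

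The GABAergic lineage list was higher almost throughout. Of its 16 measured genes 14 rose, 1 fell and 1 did not pass (15, 1 and 0 adjusted over the list alone), with a median log2 difference of 4.58, or 3.29 with dim signals at the 40th percentile of their array (camera adjusted p = 2.28e-18, and adjusted p = 5.86e-04 with an estimated correlation). The homeobox gene Dlx1 was 169-fold higher (SE 0.18 on the log2 scale, adjusted p = 3.75e-20), Dlx2 80.7-fold, Dlx5 at least 69.9-fold, Dlx6 at least 3.72-fold and Gad2 at least 117-fold. The antisense transcripts Dlx1as and Dlx6os1 were at least 333-fold and 116-fold higher. Of the 20 measured MGE interneuron genes 15 rose and 0 fell (16 and 0 adjusted over the list alone; camera adjusted p = 2.48e-15, and adjusted p = 0.0201 with an estimated correlation). Lhx6, the transcription factor of MGE-derived interneurons, read 15.85 ± 0.49 (n = 10) against 7.35 ± 1.55 (n = 5), at least 226-fold higher. The neuropeptides Sst and Npy were at least 138-fold and 71.5-fold higher, Calb1 at least 123-fold and Nxph1 at least 96.7-fold. The GFP-negative arrays above their own 40th percentile were 0 of 5 for Slc32a1 and Nxph1, 1 for Gad1, Gad2, Dlx6 and Dlx6os1, 2 for Lhx6, Calb1 and Npy, and 3 for Dlx1as, Dlx5 and Sst. Nkx2-1, which is switched off in interneurons bound for the cortex, was dim in both groups and did not pass (6.60 ± 1.13, n = 10, against 6.36 ± 1.1, n = 5; adjusted p = 0.831).

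Markers of other ventral neurons gave a mixed picture. Of 11 measured CGE interneuron genes 5 rose and 1 fell (5 and 2 adjusted over the list alone), and the list as a set did not pass (camera adjusted p = 0.0552, and adjusted p = 0.0982 with an estimated correlation), though it did, among other settings, with the 18S class as a term (0.0315), within the high (0.0482) and the low class (0.0306), and with no filter or a stricter one (0.0358 each). Fry, a test against no change, also called the list (adjusted p = 6.10e-07). Htr3a, a serotonin receptor channel, was 4.87-fold and Adarb2 14.9-fold higher, while the cannabinoid receptor Cnr1 was 4.06-fold lower. Of 20 striatal projection neuron genes 5 rose and 3 fell (6 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.119), though it did with a stricter filter (0.016) and in low 18S arrays alone (0.0192). Tested against no change with fry, the striatal list passed (adjusted p = 0.0279). Tac1 was 20.1-fold and Gucy1a1 19.0-fold higher. Isl1, a transcription factor of striatal neurons, was at least 14.0-fold higher, and Ebf1 did not pass (8.64 ± 2.09, n = 10, against 8.59 ± 0.50, n = 5; adjusted p = 0.973). Isl1 and Ebf1 lay at their highest on the arrays labelled cortex GFP-positive replicates 7 and 8, and without those arrays Isl1 read 10.77 ± 0.51 (n = 8) and Ebf1 7.73 ± 0.95 (n = 8). In low 18S arrays without them the log2 difference of Ebf1 was −1.23 (adjusted p = 0.00731).

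Genes of the cortical glutamatergic lineage were lower in GFP-positive arrays. Of 26 cortical projection neuron genes 20 fell and 3 rose (21 and 3 adjusted over the list alone; median −2.57, or −2.34 with dim signals at the percentile, camera adjusted p = 8.19e-11, and adjusted p = 0.0497 with an estimated correlation). The glutamate transporter Slc17a6 was 40.4-fold lower, Tbr1 12.1-fold, Neurod1 14.0-fold and Rnd2 6.35-fold. Of 19 pallial progenitor genes 17 fell and 1 rose (17 and 1 adjusted over the list alone; median −3.38, camera adjusted p = 3.23e-12, and adjusted p = 0.0282 with an estimated correlation). Neurog2, a proneural factor of the cortex, was 19.1-fold lower, Eomes 13.8-fold, Emx1 15.8-fold, Lhx2 11.9-fold and Pax6 2.23-fold. Of 25 radial glia genes 22 fell and 2 rose (22 and 2 adjusted over the list alone; median −2.18, camera adjusted p = 2.34e-12, and adjusted p = 0.038 with an estimated correlation). Fabp7 was 3.87-fold and Ttyh1 10.6-fold lower. Gja1, a gap junction protein, and Mmd2, Plpp3 and Lpl, all outside the lists, were 16-fold, 15.6-fold, 14.7-fold and 12.8-fold lower.

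Cell division genes were lower too, though the call of the list was lost with an estimated correlation (adjusted p = 0.3). Of 39 measured cell cycle genes 34 fell and 0 rose (38 and 0 adjusted over the list alone). Their median was −1.30 (camera adjusted p = 8.19e-11). Mki67, a marker of dividing cells, was 2.94-fold, Ccna2 3.10-fold and Cdk2 4.59-fold lower. Mki67 read 13.64 ± 0.99 (n = 10) against 15.20 ± 0.11 (n = 5), and without replicates 7 and 8 of the GFP-positive group 13.18 ± 0.26 (n = 8), where all 39 genes fell.

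Receptor and guidance genes moved in both directions. Of 29 GABA and glutamate receptor and chloride transporter genes 14 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 1.12e-06, but adjusted p = 0.0504 with an estimated correlation). The chloride exporter Slc12a5 was 12.1-fold, the AMPA receptor subunit Gria4 15.2-fold and the kainate receptor subunit Grik1 at least 31.6-fold higher. Of 56 axon guidance and migration genes 17 rose and 19 fell (19 and 21 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.986). Its median log2 difference was 0.07, while its mean was −0.21 and camera's direction was down. The chemokine receptor Ackr3 was 8.86-fold and the netrin receptor Unc5c 4.78-fold higher, whereas the chemokine Cxcl12 was 12.3-fold and the reelin adaptor Dab1 5.62-fold lower. Of 11 Cajal-Retzius genes 3 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.788), with Nhlh2 12.2-fold lower.

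Some markers of mural and meningeal and of erythroid cells were lower in GFP-positive arrays, and both list calls were lost with an estimated correlation (adjusted p = 0.323 and 0.26). Of the endothelial, microglia and oligodendrocyte markers Slc2a1 and Cnp passed. Of 17 mural and meningeal genes 5 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.0165), with Fn1 6.69-fold and Pdgfrb at least 1.96-fold lower (4 of 10 GFP-positive arrays above their 40th percentile). Of 7 erythroid genes 3 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.0145), with Alas2 at least 3.82-fold lower and the embryonic globin Hbb-bh1 at least 1.71-fold lower (1 of 10 GFP-positive arrays above the percentile for each). Of 16 endothelial genes 1 fell, Slc2a1 (3.55-fold), and 0 rose (the same adjusted over the list alone; camera adjusted p = 0.343). None of 13 microglia genes passed in limma, also adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05 (camera adjusted p = 0.451), with Csf1r at 9.46 ± 0.78 (n = 10) and 10.08 ± 1.25 (n = 5), lower past the threshold with array weights (0.0343). Of 8 oligodendrocyte lineage genes 1 rose, Cnp (1.57-fold), and 0 fell, also adjusted over the list alone (camera adjusted p = 0.905). Without cortex GFP-negative replicate 3 Cnp did not pass (adjusted p = 0.0591), nor did the mural and meningeal list without replicate 1 (camera adjusted p = 0.0639). Cnp was also lost with the RNA quality covariate (0.0947) and with the mean of its probe sets (0.582), Pdgfrb with the covariate (0.0832) and in low 18S arrays alone (0.224), and the mural and meningeal list with the 18S class as a term (0.0552), a stricter filter (0.136) and low 18S arrays alone (0.0966). Hbb-bh1 (0.193) and the erythroid list (0.121) were lost in high 18S arrays alone, and Mki67 (0.0816) in low 18S arrays alone. Of 24 immediate early and stress genes 6 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.879): Dusp1 was 1.60-fold higher, Btg2 4.67-fold and Ier2 3.30-fold lower. Of 12 apoptosis genes 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.247), with Ccng1 2.44-fold higher and Bcl2 1.93-fold lower. Fry, a test against no change, called the apoptosis list higher (adjusted p = 8.03e-05).

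RNA quality differed between these groups. The mean log2 ratio of 3' to 5' control signal, higher where RNA is more degraded or less fully copied, was 2.46 ± 0.28 (n = 10) in GFP-positive and 1.86 ± 0.14 (n = 5) in GFP-negative arrays, a difference of 0.60 (exact permutation p = 0.002, adjusted over 3 comparisons 0.006). This p counts near-identical arrays as separate. Of these, replicates 6, 9 and 10 had the highest ratios of the GFP-positive group (2.74, 2.90 and 2.78). With Actb alone the difference was 0.28 (exact permutation p = 0.139). With the 18S class as a term 5015 genes passed, and the median log2 difference was 4.54 for the GABAergic lineage list and −3.19 for the pallial progenitor list. Within the high class 2997 passed (3 against 3 arrays) and within the low class 3658 (7 against 2), and the median of the GABAergic lineage list was 4.07 and 5.02 and that of the pallial progenitor list −2.87 and −3.54. Without replicates 7 and 8 of the GFP-positive group 4467 genes passed. Median centring gave 1886 higher and 1807 lower genes, and quantile normalization 1951 and 2108, so the balance of higher and lower genes moved with the scaling.

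**Figure D1:**
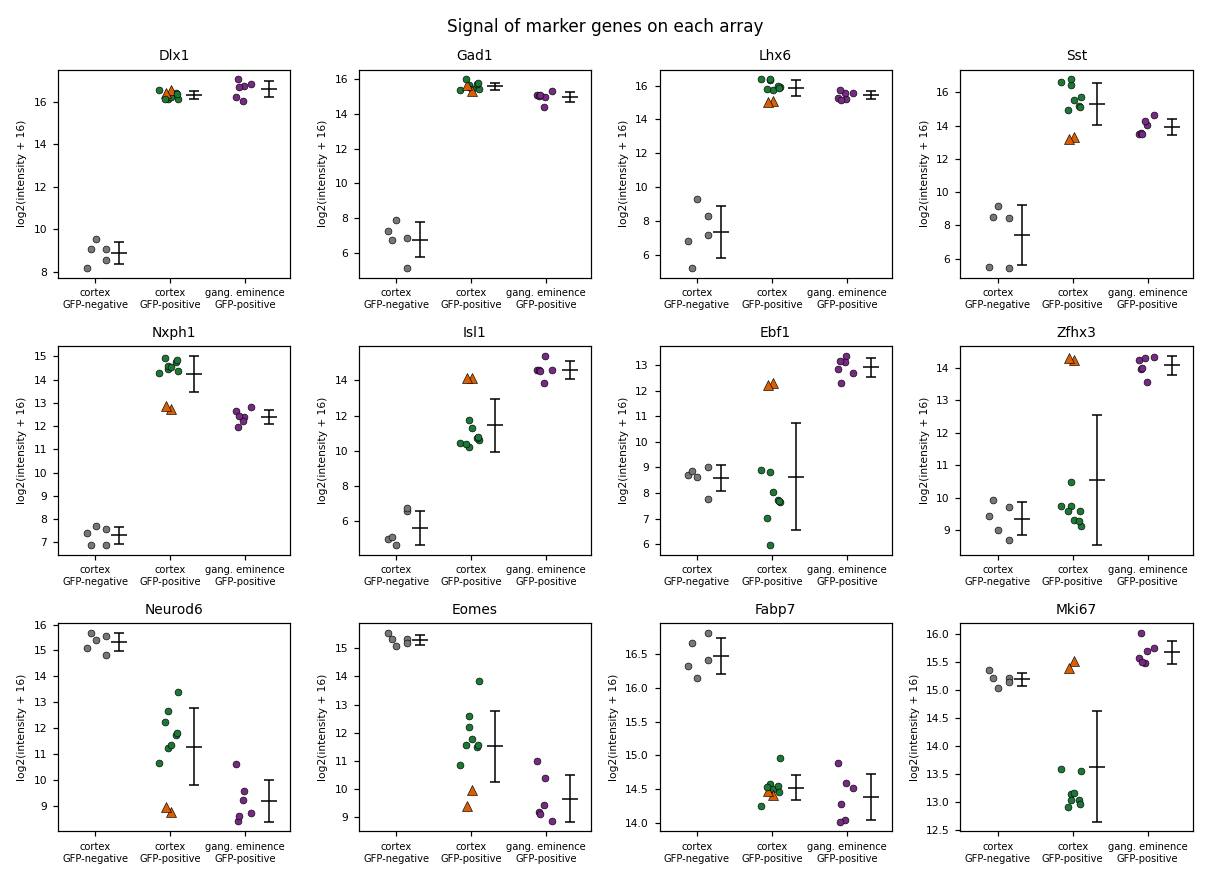
Signal of 12 genes on each of the 21 arrays, as log2(intensity + 16), by group, with the mean and SD of the group beside the points. Orange triangles are the arrays labelled cortex GFP-positive replicates 7 and 8, which sit with the ganglionic eminence arrays for Isl1, Ebf1, Zfhx3 and Mki67.

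Between GFP-positive cells of the cortex and of the ganglionic eminences, the cortex arrays had more of the transcripts of MGE-derived interneurons and less of those of dividing cells and striatal neurons. With an estimated correlation these 3 lists no longer passed (adjusted p = 0.0577, 0.0627 and 0.0684). Nxph1 was 3.55-fold higher in the cortex (14.23 ± 0.78, n = 10, against 12.40 ± 0.30, n = 6; adjusted p = 0.00102), and Mki67 4.10-fold lower (13.64 ± 0.99, n = 10, against 15.68 ± 0.20, n = 6; adjusted p = 0.00102). Ebf1, a transcription factor of striatal neurons, was 19.4-fold lower (8.64 ± 2.09, n = 10, against 12.91 ± 0.38, n = 6; adjusted p = 0.00102). Of 13668 genes, 1439 passed the threshold, 594 higher and 845 lower in the cortex, and 159 and 546 differed at least 2-fold.

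The arrays labelled cortex GFP-positive replicates 7 and 8 enter those values, although they resembled the ganglionic eminence arrays. Ebf1 read 12.31 and 12.22 on them, against 7.73 ± 0.95 on the other 8. Without these arrays 2284 genes passed, 950 higher and 1334 lower, and 1415 of the 1439 genes were among them. Nxph1 was then 4.56-fold higher (adjusted p = 1.64e-09), Mki67 5.63-fold lower (adjusted p = 4.34e-12) and Ebf1 36.4-fold lower (adjusted p = 3.02e-10). Since the arrays were left out for that resemblance, larger folds for genes that separate the groups follow from the choice.

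Of the 16 GABAergic lineage genes 2 were higher, 4 lower and 10 did not pass (4, 6 and 6 adjusted over the list alone; camera adjusted p = 0.355). Dlx1 (16.30 ± 0.18, n = 10, against 16.59 ± 0.39, n = 6; adjusted p = 0.311), Dlx2 (adjusted p = 0.829), Dlx5 (0.723), Gad1 (0.132) and Gad2 (0.934) did not pass, and median centring turned the sign of Dlx2, Dlx5 and Gad2. Npas1, a transcription factor of interneurons, was 3.46-fold higher in the cortex, and Dlx6 2.05-fold lower (adjusted p = 0.0435). Dlx6 did not pass with median centring (adjusted p = 0.0595), nor with quantile normalization. Of 20 MGE interneuron genes 12 were higher and 2 lower (15 and 2 adjusted over the list alone; median 1.05, camera adjusted p = 9.03e-09, but adjusted p = 0.0577 with an estimated correlation). Maf was 3.87-fold, Satb1 2.17-fold and Ackr3 2.73-fold higher. Lhx6 did not pass (15.85 ± 0.49, n = 10, against 15.41 ± 0.24, n = 6; adjusted p = 0.503), nor did Nkx2-1 (adjusted p = 0.356). The peptide genes Sst and Npy did not pass over all arrays (adjusted p = 0.123 and 0.165), and without replicates 7 and 8 they were 3.69-fold and 2.73-fold higher (adjusted p = 0.00775 and 0.0012). Of 11 CGE interneuron genes 1 was lower, Prox1 (5.67-fold), and 0 higher, also adjusted over the list alone (camera adjusted p = 0.78).

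Striatal and dividing-cell transcripts were lower in the cortex. Of 20 striatal projection neuron genes 13 were lower and 1 higher, also adjusted over the list alone (median −1.44, or −1.26 with dim signals at the percentile, camera adjusted p = 5.26e-09, but adjusted p = 0.0684 with an estimated correlation). Isl1 was 8.83-fold, Foxp1 3.99-fold and Zfp503 at least 9.19-fold lower (4 of 10 cortex arrays above their 40th percentile). Zfhx3 and Pou3f1, transcription factors outside the lists, were 11.6-fold and 7.53-fold lower. Of 39 cell cycle genes 33 were lower and 0 higher (37 and 0 adjusted over the list alone; median −1.63, camera adjusted p = 3.94e-29, but adjusted p = 0.0627 with an estimated correlation), and all 39 were lower without replicates 7 and 8. Ube2c was 4.93-fold, Kif20a 4.99-fold, Cdc25c 5.16-fold and Ccna2 3.63-fold lower. Hmmr and Anln, mitotic genes outside that list, were 5.46-fold and 5.11-fold lower. Of 25 radial glia genes 9 were lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.00376, but adjusted p = 0.323 with an estimated correlation). Notch1 was 4.22-fold and Vim 1.80-fold lower, and Aldoc was 3.76-fold higher. Of 8 oligodendrocyte lineage genes 5 were lower and 0 higher (6 and 0 adjusted over the list alone; camera adjusted p = 2.00e-04, but adjusted p = 0.0577 with an estimated correlation), with Olig2 at least 3.62-fold and Sox8 at least 2.4-fold lower (2 of 10 cortex arrays above the percentile for each).

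Some pallial transcripts were higher in the cortex arrays. Of 19 pallial progenitor genes 7 were higher and 1 lower (9 and 1 adjusted over the list alone; median 0.82, or 0.32 with dim signals at the percentile, camera adjusted p = 6.43e-06, but adjusted p = 0.099 with an estimated correlation), and of 26 cortical projection neuron genes 5 were higher and 1 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.0426, but adjusted p = 0.506 with an estimated correlation). Neurog2 was 5.08-fold, Neurod6 4.28-fold, Eomes 3.65-fold, Tfap2c 3.04-fold and Wnt7b 2.54-fold higher. Cortex replicate 2 read highest of the 10 arrays for these 5 genes, and without it their log2 differences were 2.13, 1.86, 1.61, 1.43 and 1.21 in that order (adjusted p from 0.00946 to 0.0174), while the cortical projection neuron list did not pass (camera adjusted p = 0.205). Mef2c, a member of the MGE and the projection neuron lists, was 3.15-fold higher. Emx1 (adjusted p = 0.214), Tbr1 (0.369) and Pax6 (0.474) did not pass.

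Some receptor, guidance and immediate early genes passed, in either direction. Of 29 receptor and transporter genes 6 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0202, but adjusted p = 0.323 with an estimated correlation), with Gria1 4.53-fold, Gria4 2.79-fold and the metabotropic glutamate receptor Grm5 4.44-fold higher. Neto1, an auxiliary subunit of kainate receptors, was 3.72-fold and the RNA-binding protein gene Rbms3 3.86-fold higher. Of 56 axon guidance and migration genes 11 were higher and 10 lower (13 and 13 adjusted over the list alone; camera adjusted p = 0.986), and the median was −0.17 while camera's direction was up. Epha5 was 2.63-fold higher, Ephb1 4.5-fold and Ntn1 (netrin) 8.87-fold lower. Of 24 immediate early and stress genes 4 were higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.0552). Fos was 3.54-fold and Egr1 4.14-fold higher, and Gadd45g 2.43-fold lower. Of 11 Cajal-Retzius genes 2 were higher, Reln (1.91-fold) and Cxcr4 (2.37-fold), and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0987). Of 12 apoptosis genes 1 was higher, Ccng1 (1.5-fold), and 0 lower, also adjusted over the list alone (camera adjusted p = 0.272). Fry, a test against no change, called the immediate early (adjusted p = 0.0168) and apoptosis (0.0255) lists higher in the cortex. With dim signals at the percentile, however, the median log2 difference of the immediate early list went from 0.245 to −0.038. That of the apoptosis list went from 0.122 to 0.131.

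Markers of non-neural cells passed in few cases. Of 16 endothelial genes 1 was lower, Sox18 (at least 1.82-fold, 3 of 10 cortex arrays above their 40th percentile), and 0 higher (2 and 0 adjusted over the list alone; camera adjusted p = 0.00726, but adjusted p = 0.323 with an estimated correlation). Of 17 mural and meningeal genes 3 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.15), with Fn1 2.21-fold lower and the collagen Col3a1 at least 1.62-fold higher (1 of 6 ganglionic eminence arrays above its 40th percentile). None of 13 microglia genes passed in limma, also adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05, while the list passed (direction down, camera adjusted p = 0.0165, but adjusted p = 0.323 with an estimated correlation). Of 7 erythroid genes 2 were lower and 0 higher (3 and 0 adjusted over the list alone; camera adjusted p = 0.0165, but adjusted p = 0.28 with an estimated correlation), with Hbb-bh1 at least 1.16-fold lower (1 of 10 cortex arrays above the percentile).

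Some calls of this comparison were lost with 1 array left out. Dlx6 did not pass without cortex replicate 1, 2, 6, 9 or 10 or ganglionic eminence replicate 2, 3, 4 or 6 (adjusted p from 0.054 to 0.127). Cxcr4 did not pass without any 1 of the cortex arrays other than 7 and 8, or without ganglionic eminence replicate 2, 3, 4, 5 or 6 (from 0.054 to 0.0939). Hbb-bh1 did not pass without cortex replicate 4, 6, 9 or 10 or ganglionic eminence replicate 1, 2, 3 or 5 (from 0.0631 to 0.0762), nor Sox18 without cortex replicate 6, 9 or 10 or ganglionic eminence replicate 3, 4 or 6 (from 0.051 to 0.0883). The cortical projection neuron list did not pass without cortex replicate 1 or 2 or ganglionic eminence replicate 4, 5 or 6 (camera adjusted p from 0.0591 to 0.205). Without ganglionic eminence replicate 3 the endothelial (0.064) and erythroid (0.0514) lists did not pass, nor the microglia list without replicate 2 or 3 (from 0.0552 to 0.0621).

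Calls of this comparison were also lost under other settings (adjusted p in brackets). With near-identical arrays averaged these were Dlx6 (0.13), Sox18 (0.107), Hbb-bh1 (0.102) and the erythroid list (0.0609). With the mean of a gene's probe sets they were Aldoc (0.125), Wnt7b (0.498), Tfap2c (0.231), Reln (0.164), Grm5 (0.312) and Ccng1 (0.164). The RNA quality covariate lost Dlx6 (0.0691), Cxcr4 (0.0588), Hbb-bh1 (0.0584) and the cortical projection neuron list (0.124). Median centring also lost Fn1 (0.0629), Hbb-bh1 (0.0661) and the projection neuron (0.11) and receptor (0.1) lists, and quantile normalization Dlx6 (0.0566), Hbb-bh1 (0.213) and the projection neuron (0.0845) and microglia (0.111) lists. A fit of the 2 groups alone lost Cxcr4 (0.069), Sox18 (0.0565), Hbb-bh1 (0.0573) and the projection neuron list (0.0579). That list was also lost with a stricter filter (0.136), together with the endothelial list (0.0868), and with the 18S class as a term (0.0574). Fry, a test against no change, did not call it (0.268) or the receptor list (0.109). Without a trend in eBayes Dlx6 (0.0507) and Cxcr4 (0.0637) were lost, with a floor of 1 Dlx6 (0.0545), with no filter Dlx6 (0.0602) and the erythroid list (0.0685), and with the largest pseudocount Col3a1 (0.0858) and Hbb-bh1 (0.0938). Without cortex replicates 7 and 8 the microglia (0.0668) and erythroid (0.0555) lists were lost, as they were with the 18S class also a term (0.0766 and 0.0644). Without them and with near-identical arrays averaged, 3 named genes were lost, among them Dlx6 (0.122) and Sox18 (0.138), and the endothelial (0.0527) and erythroid (0.135) lists. Without them in low 18S arrays, 1 named gene and the endothelial (0.0752) and microglia (0.112) lists were lost. In high 18S arrays alone, 3 against 2, Dlx6 (0.214), Sox18 (0.0742), Col3a1 (0.0914), Hbb-bh1 (0.651), Sox8 (0.0974), Fos (0.0668), Ccng1 (0.0888) and the projection neuron (0.269), microglia (0.136) and erythroid (0.339) lists were lost. Calls were gained too, of which some are given here. Sst (0.00654) and Npy (0.0419) passed with the 18S class as a term, and Gad1 in a fit of the 2 groups alone (0.012). Array weights gained 4 named genes, among them Tbr1 (0.0466). Lhx6 (0.0168) and Pax6 (0.0112) passed in low 18S arrays without replicates 7 and 8, and the Cajal-Retzius list (0.03) without those replicates. Over all arrays the median log2 difference of that list was 0.250, but −0.090 with dim signals at the percentile.

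The balance of higher and lower genes in this comparison moved with the scaling. Median centring shifted the median of all genes by 0.23 on the log2 scale and gave 1068 higher and 441 lower genes, and quantile normalization shifted it by 0.11 and gave 645 and 609. The folds are relative to the deposited scaling. RNA quality differed by 0.20 (exact permutation p = 0.293). Within the high 18S class 1054 genes passed (3 against 2 arrays). Within the low class 0 passed (7 against 4; limma, 3170 at an unadjusted p under 0.05), and 2510 passed there without replicates 7 and 8 (5 against 4). With the class as a term 2264 passed. The median log2 difference of the MGE interneuron list was 1.06 with the class as a term, 1.59 in the high class and 0.93 in the low class, and that of the cell cycle list −1.65, −2.11 and −1.48.

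**Figure D2:**
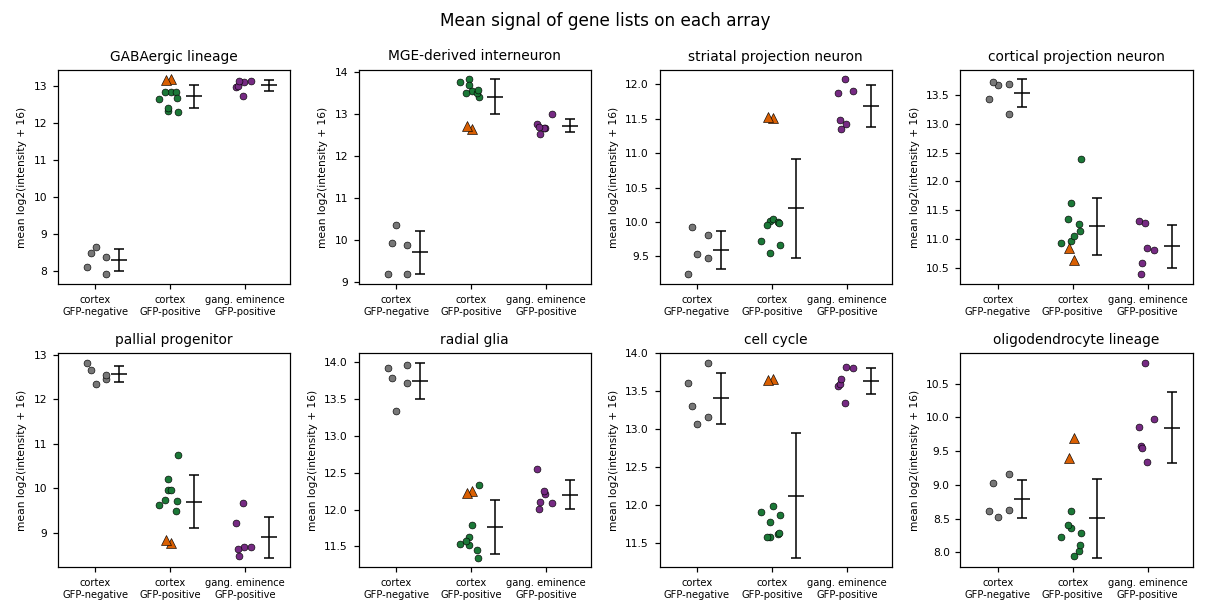
Mean log2(intensity + 16) over the measured genes of 8 lists on each array, by group, with the mean and SD of the group beside the points. Orange triangles are the arrays labelled cortex GFP-positive replicates 7 and 8. The GABAergic lineage list separates both GFP-positive groups from the GFP-negative arrays, and the cell cycle list is lowest on the other 8 cortex GFP-positive arrays.

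GFP-positive cells of the ganglionic eminences had more of the transcripts of the GABAergic lineage, of MGE interneurons and of striatal neurons than GFP-negative cells of the cortex, and less of those of projection neurons, pallial progenitors and radial glia, with region and reporter changing together. Of these 6 lists the striatal one no longer passed with an estimated correlation (adjusted p = 0.0906). Isl1 was at least 123-fold higher (14.59 ± 0.49, n = 6, against 5.61 ± 0.97, n = 5; adjusted p = 8.86e-11), Slc32a1 at least 101-fold higher, and Neurog2 96.9-fold lower (8.55 ± 0.97, n = 6, against 15.15 ± 0.14, n = 5; adjusted p = 2.71e-08). Mki67 did not pass (15.68 ± 0.20, n = 6, against 15.20 ± 0.11, n = 5; adjusted p = 0.452), and without cortex GFP-positive replicates 7 and 8 in the shared fit it was 1.39-fold higher (adjusted p = 0.0209), and it passed in a fit of the 2 groups alone (0.0234). Of 13668 genes, 2341 passed, 1139 higher and 1202 lower, and 746 and 737 differed at least 2-fold.

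Of 16 GABAergic lineage genes 14 were higher and 1 lower, also adjusted over the list alone (median 4.34, or 3.36 with dim signals at the percentile, camera adjusted p = 1.58e-25, and adjusted p = 1.31e-04 with an estimated correlation), with Dlx6os1 at least 187-fold, Gad1 at least 159-fold and Dlx1 206-fold higher. Of 20 MGE interneuron genes 12 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 5.23e-12, and adjusted p = 0.038 with an estimated correlation), with Lhx6 at least 167-fold and Sst at least 53-fold higher. Of 20 striatal projection neuron genes 11 were higher and 1 lower (13 and 2 adjusted over the list alone; camera adjusted p = 4.95e-08, but adjusted p = 0.0906 with an estimated correlation), with Tac1 39.3-fold and Ebf1 20-fold higher. Of 11 CGE interneuron genes 5 were higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.0165, but adjusted p = 0.0547 with an estimated correlation), with Adarb2 28.5-fold higher. Of 26 cortical projection neuron genes 19 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 1.33e-16, and adjusted p = 0.0201 with an estimated correlation), with Neurod6 69.9-fold and Tbr1 18.2-fold lower. Of 19 pallial progenitor genes 16 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 3.72e-21, and adjusted p = 0.00405 with an estimated correlation), with Eomes 50.3-fold and Wnt7b 30.1-fold lower. Of 25 radial glia genes 16 were lower and 2 higher (18 and 2 adjusted over the list alone; camera adjusted p = 2.34e-11, and adjusted p = 0.0477 with an estimated correlation): Aldoc was 33.3-fold lower and Sox1 3.15-fold higher. None of 39 cell cycle genes passed in limma, also adjusted over the list alone, and 2 were higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.337). The list passed in the high 18S class alone (median 0.44, adjusted p = 0.00149), with the RNA quality covariate (0.0299), in a fit of the 2 groups alone (0.0169) and, with near-identical arrays averaged, without replicates 7 and 8 (0.0471).

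Of 29 receptor and transporter genes 13 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 3.42e-06, but adjusted p = 0.0561 with an estimated correlation), with Slc12a5 9.59-fold and Grm7 at least 12.3-fold higher (3 of 5 GFP-negative arrays above their 40th percentile). Of 56 axon guidance and migration genes 13 were higher and 15 lower (16 and 16 adjusted over the list alone; camera adjusted p = 0.986), with a median of 0.29 and a mean of −0.01. Cxcl12 was 19.8-fold lower and Efnb3 3.30-fold higher. Of 8 oligodendrocyte lineage genes 3 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0153, but adjusted p = 0.2 with an estimated correlation), with Olig2 at least 5.07-fold higher (2 of 5 GFP-negative arrays above the percentile). Olig2 did not pass without cortex GFP-negative replicate 3 or 5 or ganglionic eminence replicate 3 or 6 (adjusted p from 0.0523 to 0.0702), nor with the RNA quality covariate (0.0606), a floor of 1 (0.0548) or low 18S arrays alone (0.273). With the mean of a gene's probe sets, 1 named gene of this comparison lost its call. The lists of Cajal-Retzius cells (2 higher and 4 lower of 11, camera adjusted p = 0.15), immediate early and stress genes (0 and 6 of 24, 0.105), apoptosis (3 and 2 of 12, 0.513), endothelial cells (0 and 1 of 16, 0.505), microglia (0 and 0 of 13 in limma, also 0 at an unadjusted p under 0.05, 0.45) and erythroid cells (0 and 1 of 7, 0.195) did not pass, with the same counts adjusted over the list alone, though the immediate early list did with the RNA quality covariate (0.0399), with no filter (0.0311) and with fry (0.00134), and the Cajal-Retzius (0.0202) and apoptosis (0.0279) lists with fry. Nor did mural and meningeal genes (1 and 3 of 17, and 1 and 5 adjusted over the list alone; 0.0987, but 0.0258 with array weights, 0.0404 with no filter and 0.0339 with quantile normalization), of which Col3a1 was at least 6.06-fold lower (1 of 6 ganglionic eminence arrays above the percentile). Trp73, a Cajal-Retzius gene, was at least 3.05-fold lower (2 of 6 arrays above it) and the immediate early gene Ier2 3.83-fold lower, and the cell cycle inhibitor Cdkn1a, of the apoptosis list, was 2.74-fold higher. With dim signals at the percentile, the median log2 difference of the mural and meningeal list went from −0.391 to 0.037. For the immediate early list it went from −0.136 to 0.044, for Cajal-Retzius from −0.621 to −0.076 and for apoptosis from 0.252 to 0.302. Median centring shifted the median of all genes by −0.14 and gave 788 higher and 1325 lower genes. RNA quality differed by 0.40 (exact permutation p = 0.0823). Within the high 18S class 1540 genes passed (2 against 3 arrays), within the low class 2012 (4 against 2), and with the class as a term 3411. The median of the GABAergic lineage list was 4.12, 4.89 and 4.36 in that order, and that of the pallial progenitor list −3.72, −4.18 and −3.91.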

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

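A single array stood far from the rest of its group in 21 of 378 groups of values looked at (named genes, list means and RNA quality ratios), or 5.56%, where chance gives about 1 in 20. Values are log2(intensity + 16) unless stated, each with the next array of its group. No explanation was tested. The kind of check was not chosen after the result was seen, but the named genes it covered were a part chosen after the values were seen. The rate depends on that choice.

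Cortex GFP-positive replicate 2 was high for 4 genes that were lower in GFP-positive than in GFP-negative arrays: Plpp3 (12.59, next 11.27), Lpl (13.66, next 11.69), Fabp7 (14.96, next 14.58) and Ttyh1 (12.49, next 11.17). It also had the highest Actb 3' to 5' log2 ratio of its group (2.64, next 2.12). The array labelled cortex GFP-positive replicate 7 was low for Emx1 (6.16, next 8.07).

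Ganglionic eminence GFP-positive replicate 3, whose median intensity of 988 was the highest of the 21 arrays (next 416), was high for Cnp (12.82, next 11.96), for the mean of the Cajal-Retzius list (9.98, next 9.24) and for the mean of the erythroid list (10.11, next 8.68). Its median correlation with the other arrays was the lowest (0.807, next 0.908), and its mean 3' to 5' log2 ratio the highest (2.94). The array was kept. Without it 1113 genes passed for cortex against ganglionic eminence and 2457 for ganglionic eminence against cortex GFP-negative. Replicate 2 of that group was high for Grm5 (11.05, next 10.24).

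Among the 5 cortex GFP-negative arrays, replicate 4 was low for Slc32a1 (4.83, next 5.74), Neurod1 (13.52, next 14.55), Reln (14.64, next 14.89) and the Gapdh 3' to 5' log2 ratio (1.37, next 2.09). Replicate 1 was high for Cxcl12 (13.66, next 12.84) and Pdgfrb (9.50, next 8.83) and low for Sox8 (4.49, next 7.99). Replicate 2 was high for Npas1 (5.70, next 5.17) and Mef2c (13.81, next 13.35). Replicate 3 was low for Calb1 (4.78, next 7.38) and Grm7 (5.17, next 7.31).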

How the results depend on the processing

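No paired analysis was possible because replicate numbers were given in accession order and tie no arrays together. Alternatives with replicates 7 and 8 of the cortex GFP-positive group left out, with the 18S or Xist class, with averaged arrays or with a larger pseudocount were chosen after seeing the data. In what follows A is cortex GFP-positive against cortex GFP-negative (4292 genes), B cortex against ganglionic eminence GFP-positive (1439) and C ganglionic eminence GFP-positive against cortex GFP-negative (2341). Array weights gave 6500 genes in A and 2628 in B. Counting probe sets gave 7124 in A and 3711 in C, by testing 31056 probe sets. A difference of at least 1 on the log2 scale left 2298, 705 and 1483, and an adjusted p under 0.01 left 543 in B and 1529 in C, by construction. Without replicates 7 and 8, B had 2284 genes. The 18S class as a term gave 2264 in B, and with 7 and 8 also left out 3297 in B and 3622 in C. High 18S arrays alone gave 1540 in C, and low 18S arrays alone 0 in B (limma, 3170 at an unadjusted p under 0.05). Low 18S arrays without 7 and 8 gave 2510 in B. With 1 array left out in turn, the counts ran from 3696 to 4749 in A, from 975 to 1787 in B and from 1999 to 2457 in C. An estimated correlation left 10 of the 54 list tests past the threshold, against 29 with the preset one, where leaving out 1 array gave 28 to 31. The RNA quality difference in A fell to 0.28 with Actb alone (exact permutation p = 0.139), in B it was −0.072 with Actb alone, and with 1 array left out it ran from 0.55 to 0.66 in A, from 0.10 to 0.33 in B and from 0.27 to 0.50 in C, where the exact permutation p was 0.0476 without ganglionic eminence replicate 4 (0.493) and 0.0317 without 6 (0.503), or 0.0714 and 0.0476 adjusted over 3 comparisons. Ebf1 in A was −1.23 (adjusted p = 0.00731) in low 18S arrays without replicates 7 and 8 (0.04 in the main setting). Beyond the choices whose construction shows it, the cause was not tested. Of the named-gene values under all alternatives, 7321 kept direction and side of the threshold, 157 lost the threshold, 45 passed it and 25 changed sign without passing in either. These genes were chosen after the values were seen, and many alternatives leave out 1 array only. A large number kept was therefore likely beforehand. Of the 157 losses, 50 fell in B with low 18S arrays alone, where 13 values kept direction and side. The dimmest genes are limited by the array background, for which the 40th percentile was used as a stand-in. That percentile was 665 on ganglionic eminence replicate 3 and from 142 to 245 on the other arrays.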

Other observations

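The counts over other splits of the arrays and the fit with the 3' to 5' ratio as a covariate were planned, while the bound set on the calls kept in that fit and the other tests of this part were chosen after the result was seen. Each explanation below is a hypothesis.

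GFP-positive cells of the cortex and of the ganglionic eminences were also compared without the arrays labelled cortex GFP-positive replicates 7 and 8. Those arrays were left out because they resembled the ganglionic eminence arrays, so a larger fold than over all arrays is no independent evidence. In that comparison the chemokine receptor Cxcr4 was 3.33-fold higher in the cortex (13.76 ± 0.17, n = 8), Gria1 6.53-fold, Maf 5.84-fold and Npas1 4.53-fold. Zfhx3 was 22.1-fold and Zfp503 at least 15.9-fold lower (2 of 8 cortex arrays above their 40th percentile). The cortical gene Emx1 was 2.84-fold higher (adjusted p = 0.00719). The counts for the lists were 15 higher and 2 lower of 20 MGE interneuron genes, 10 higher and 1 lower of 19 pallial progenitor genes, and 10 higher and 3 lower of 26 cortical projection neuron genes.

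The arrays labelled cortex GFP-positive replicates 7 and 8 lie with the ganglionic eminence arrays. On an axis of 100 genes computed without them and without the array placed, from 0 (the other 8 cortex GFP-positive arrays) to 1 (ganglionic eminence), they stood at 1.014 and 1.009. The other 8 lay between −0.084 and 0.156 and the ganglionic eminence arrays between 0.899 and 1.038. Ganglionic eminence replicate 5, to which replicates 7 and 8 were close, helped to set the axis on which they were placed. If they repeat its RNA, their positions are not independent of the axis. A mixture of cortical with some ganglionic eminence cells would lie between the groups, and the mean of 1.012 argues against it, while the lowest ganglionic eminence position of 0.899 argues against an exchange with one of those arrays. RNA of ganglionic eminence cells under a cortex label could give the lower position of 1.009. Whether it arose at dissection, sorting or labelling, or as repeat arrays of the RNA of ganglionic eminence replicate 5, stays open.

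Pallial genes read higher in cortex than in ganglionic eminence GFP-positive arrays, and a candidate explanation is a share of GFP-negative cells carried through the sort. The genes used here passed the threshold at least 4-fold lower in ganglionic eminence than in cortex GFP-negative arrays. They also had a mean at or above the median of the cortex GFP-negative values. The same ganglionic eminence values set the 0% level, so this choice can raise the shares. Taking the ganglionic eminence level as 0% and the cortex GFP-negative level as 100% on the linear scale, the median share averaged 5.38% for 15 projection neuron genes and 6.40% for 12 pallial progenitor genes over 8 arrays, a difference of −1.02 percentage points (SD 4.19, exact sign-flip permutation p = 0.531). These values rest on replicate 2, at 24.9% and 16.3%: without it they were 2.6% and 4.98%, a difference of −2.38 (SD 1.77, n = 7, lower for projection neuron genes in 6 of 7 arrays, exact sign-flip permutation p = 0.0312). Replicate 2 was left out after its values were seen, and this p counts near-identical arrays as separate. With the near-identical replicates 6, 9 and 10 also averaged the p was 0.125, where 5 values allow no less than 0.0625, so the test cannot decide on 1 even share. Over the 8 arrays the mean share of single genes ran from −7.91% (Rnd2) to 44.1% (Zfpm2), both projection neuron genes. Over 171 genes at least 4-fold lower in the ganglionic eminence arrays the median share was 16.8% on replicate 2 and from −0.530% to 2.75% on the other 7, and with that few independent arrays and no marker of the carried cells an even share cannot be told apart from low expression by the sorted cells, which was not tested.

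Most genes past the threshold between cortex GFP-positive and GFP-negative arrays stayed past it with the 3' to 5' ratio or the 18S class in the fit. The ratio comes from Gapdh and Actb only and differed between the groups. A fit with it therefore cannot exclude RNA quality as a cause. With the 3' to 5' ratio as a covariate 63.2% of the calls stayed past the threshold, the median called difference was 96.5% of its former size, and the median SE was 1.29 times the former. With the 18S class as a term 96.5% stayed. The ratio itself was associated with 21 genes and the class with 4764, so the class may be a labelling or scanning batch that crossed the groups. A biological difference between the sorted populations was not tested apart from the reporter.

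Other splits of the same arrays into groups of the same sizes (100 counted, the real one included) seldom gave as many genes. The splits count near-identical arrays as separate. The real split alone (1 of 100) reached the 4292 genes of cortex GFP-positive against GFP-negative arrays (highest other 1), the 1439 of cortex against ganglionic eminence (highest other 548) and the 2341 of ganglionic eminence against cortex GFP-negative (highest other 1806, in a split that set the 5 cortex GFP-negative arrays and 1 ganglionic eminence array against the other 5). Counts of lists, adjusted within a comparison, were less specific: as many as the real 9 lists came up in 23 of 100 splits for cortex GFP-positive against GFP-negative (highest other 13) and as many as the real 9 in 19 of 100 for ganglionic eminence against cortex GFP-negative (highest other 12), so chance is not excluded for those numbers. For cortex against ganglionic eminence the real 12 lists were reached in 1 of 100 (highest other 11). The median over the other splits was 6, 3 and 5 lists in the order of the report. Camera at the preset correlation thus often called lists for splits that mix the groups. A small camera p at that setting therefore does not alone tie a list to the real groups.

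Some arrays were closer to each other than the rest, across the group labels too. Over the brighter genes, cortex GFP-positive replicates 7 and 8 differed by a root mean square of 0.147 on the log2 scale, and replicates 6, 9 and 10 by 0.184 to 0.229. Replicates 7 and 8 differed from ganglionic eminence GFP-positive replicate 5 by 0.203 and 0.259, and the next closest pair, cortex GFP-negative replicates 2 and 5, by 0.308. No arrays held identical values. Replicates 6, 9 and 10, and 7 and 8, may be repeats of the same RNA, in which case n = 10 stands for 7 and n = 8 for 6, and the SDs and SEs of that group are too small. Replicate 7 was closer to ganglionic eminence replicate 5 (0.203) than the farthest pair of replicates 6, 9 and 10 (0.229). If replicates 7 and 8 repeat the RNA of that ganglionic eminence array, n = 10 stands for 6 cortex RNAs. The same RNA would then enter both GFP-positive groups. Averaging replicates 7 and 8 into 1 array and replicates 6, 9 and 10 into another, within their labelled group, gave 3736, 1150 and 2277 genes in the order of the report.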
